A study of Drosophila melanogaster with 3 samples.

How the data were processed

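The series holds 3 chromatin immunoprecipitation libraries from embryos of both sexes, 0 to 24 hours old, of a line with GFP-tagged CG13775. Per the labels' protocols, chromatin was sheared by sonication to fragments of 200 to 800 bp and precipitated with an anti-GFP antibody. All 3 libraries form a single group, and the labels mark them as biological replicates 1, 2 and 4. The deposited records name a single control file per assembly, shared by the 3 libraries, whose kind they do not state, and no control is among the deposited files. The peak caller and its version are not stated.

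For each of the assemblies dm3 and dm6, the authors deposited a relaxed list per replicate and one for the pooled libraries, both described as input for the IDR procedure and holding background regions as well as peaks, and an optimal list after the IDR threshold. Each dm6 relaxed list held 30000 regions; the optimal lists held 5862 peaks in dm6 and 5509 in dm3. Each region has a signal value that the authors' peak caller gave it, deposited without a stated scale. The q-value column was deposited as −log10 q by the convention of the format; it reached a ceiling of 3.97 that 79.2% of the dm6 optimal peaks shared, so it was not used to order peaks. Signal ranges differ between separately called lists (the median was 25.8, 17.3 and 35 in replicates 1, 2 and 4), so signal was compared only within a list, to rank regions, and a ratio of 2 signals describes that list without standing for a fold of occupancy. Among the optimal peaks, 49 repeat the interval of another peak with a different summit and were kept. Read counts are not in the files, so depth is unknown.

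Analyses used the dm6 lists, whose coordinates lie within the chromosome arms of the Release 6 assembly, with the Ensembl annotation of BDGP6. Genes on the arms X, 2L, 2R, 3L, 3R, 4 and Y were kept and transposable elements were left out of the gene set, which left 18277 genes with 23694 distinct transcript starts. The dm3 lists served for counts and replicate overlaps only, and no coordinate was converted between assemblies. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

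Replicate lists were restricted to the regions of highest signal, as many as the optimal list has, and regions were shared if they overlapped by at least 1 bp. Expected overlaps came from 100 shuffles within chromosomes. A summit was near a TSS if within 500 bp of any transcript start, and a gene was bound if an optimal summit lay within 500 bp of any of its transcript starts. Shares were compared with shares of bases by exact binomial tests, which treat peaks as independent. Gene lists and divergent pairs were compared by two-sided Fisher's exact tests, with protein-coding lists set against protein-coding genes and RNA lists against all genes. Of the listed symbols, lat, nos, calypso and SmG matched no gene and were left out. Words were sought on both strands within 50 bp of each summit and in a window of 101 bp centred 300 bp away on a random side, and compared by exact McNemar tests. All p-values of a family were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Intervals are exact (Clopper-Pearson) at 95%.

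Genes were named by a rule fixed before the data were examined: those with a TSS nearest to, and within 500 bp of, the summits of the 25 optimal peaks with the highest signal (peaks with none are named by position and nearest gene), the up to 4 bound members with the highest signal of each gene list that passed the test, and CG13775. Further genes with a start within 500 bp of those summits, the genes that hold distal summits and unbound list members were named after their values were seen. The gene lists, the words and the tests of the report were fixed at the same time, except for alternatives said to be chosen after seeing the data and for the tests of the CG13775 locus and of the word TGCGGATG, which were added after their results were seen.

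The procedures were tested on simulated data. In repeated runs over 18277 genes, 40 differences were planted, each in a list of at least 40 members, and 100% were called in the right direction. Of 440 tests of unchanged lists, 1.14% were called. No difference was planted in smaller lists and each gene was drawn independently. Power in smaller lists and the effect of clustered genes were therefore not tested. A word planted in 5% of 5862 windows was called in 5 of 5 runs, with 1 call of another word. These windows lay at random positions, without the difference in base composition between real summits and flanks. Calls that such a difference can cause were therefore not tested. With 59.6% of regions kept and the others placed at random, 64.6% were recovered at 1 bp. Chance overlaps and overlaps among the optimal peaks themselves can both add to this surplus, and they were not separated.

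Alternatives covered the dm3 lists, the upper part of the optimal list by signal, peaks supported in every replicate, other overlap rules and list lengths, TSS distances of 250 and 1000 bp, protein-coding starts only, other backgrounds, wider word windows, and leaving out each replicate in turn.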

Results

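Chromatin immunoprecipitation followed by sequencing was used to map where the protein encoded by CG13775 sits on the Drosophila melanogaster genome. The embryos came from a transgenic line that carries CG13775 with green fluorescent protein (GFP) fused to its C terminus, and the immunoprecipitation used an antibody against GFP. Whole embryos of both sexes, 0 to 24 hours old, were collected together, so each library averages over all tissues and embryonic stages. The series holds 1 group of 3 biological replicates, numbered 1, 2 and 4, and no library from an untagged line or an input. The records name a shared control file of unstated kind, which is not among the files. The deposited lists hold called regions and no reads, so the sequencing depth per library is unknown and the intervals below cover counting error over peaks or genes only. No comparison between conditions is possible, and the questions the design addresses are where the tagged protein was bound, at which genes, on which sequence, and how well the replicates agreed.

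Peaks of the tagged protein were concentrated at promoters, and the binding landscape was shared by the replicates. The deposited list of peaks that passed the irreproducible discovery rate (IDR) filter, called the optimal peaks from here on, held 5862 peaks on the dm6 assembly, with a median width of 464 bp. When each replicate's own list was restricted to its 5862 regions of highest signal, 4297 optimal peaks (73.3%) overlapped a region in every replicate. By chance, shuffled lists gave a mean of 0.32 such peaks and at most 2 in 100 shuffles. Only 27 optimal peaks overlapped none of the 3 restricted lists. The restricted lists overlapped pairwise at 81.4% ± 1.09 of their regions (SD over 3 pairs, which share libraries), against 3.6% for shuffled lists. Across optimal peaks, the rank order of signal correlated between replicates with a mean Spearman's rho of 0.821 ± 0.022 (SD over 3 pairs). That correlation is across peaks, which are not independent replicates. The optimal list was made from the same libraries, and it coincides with the 5862 regions of highest signal in the list called on the pooled libraries, so its support by the replicates is a description and no independent test.

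Peak summits gathered just upstream of transcription start sites (TSSs). Of the 5862 summits, 3137 (53.5%; exact 95% interval 52.2 to 54.8) lay within 500 bp of an annotated TSS, whereas 13.3% of the positions on the chromosome arms do. The restricted replicate lists gave 53.7% ± 3.25 (SD, n = 3), with 50.9% in replicate 1, 52.9% in replicate 2 and 57.2% in replicate 4, so the 4.02-fold excess over all positions was far larger than the spread between libraries. Of the pooled regions ranked below the optimal peaks, 28.1% lay within 500 bp of a TSS, so against this background, chosen after seeing the data, the excess was smaller (Fisher's exact p = 1.17e-286). Among the summits within 500 bp, 80.4% lay upstream of the nearest TSS, and the median position was −102 bp. The excess was tied to signal: in the pooled list, 61.7% of the 2500 regions with the highest signal lay within 500 bp of a TSS, and 19.6% of the 2500 with the lowest. The exact two-sided binomial p for the optimal summits was under 1e-300, and none of 10000 draws of random positions with the same number per chromosome exceeded 15.6% (p = 0.0001, the smallest these draws can give).

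**Figure D1:**
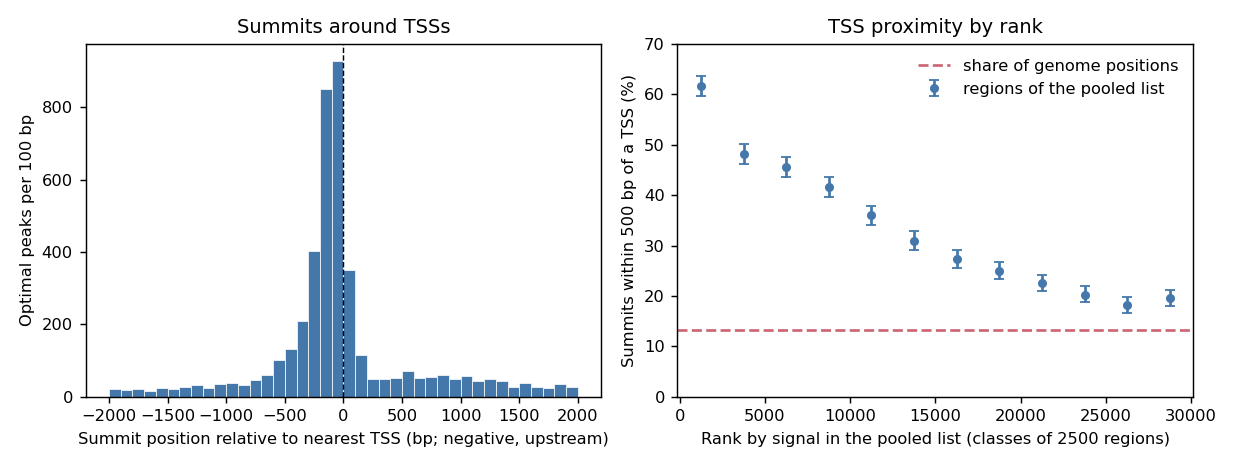
Left, number of optimal peak summits per 100 bp against their position relative to the nearest annotated TSS in bp, negative values being upstream. Right, percentage of summits within 500 bp of a TSS in successive classes of 2500 regions of the pooled list, ordered by signal, with exact 95% intervals; the dashed line is the 13.3% of genome positions that lie that close to a TSS, and the share declines from 61.7% to 19.6%.

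Away from promoters, introns held most of the peaks, and coding exons few. Each summit was assigned to a single annotation class, with TSS proximity first. Introns held 1808 summits (30.8%; 30.9% ± 2.21 in the replicates, SD, n = 3) against 39.2% of bases. Intergenic sequence held 756 (12.9%) against 28.2% of bases. Coding exons more than 500 bp from a TSS held 35 summits (0.597%) against 12.8% of bases, and 3′ UTRs held 48 (0.819%) against 4.94%. All 4 shares fell below the share of bases by exact binomial tests with Benjamini-Hochberg adjustment over 7 classes (adjusted p = 6.2e-40 for introns, 1.63e-172 for intergenic sequence, 2.25e-287 for coding exons and 4.4e-71 for 3′ UTRs). Summits near a TSS took 53.5% of the total from 13.3% of bases, so the other classes together had to fall below theirs. The intron test therefore shows no deficit away from promoters. There introns held 1808 of 2725 summits, above their share of the bases outside the 13.3% near a TSS, a comparison not itself tested. Among the 4 classes, the ratio to the share of bases was highest for introns (0.788) and lowest for coding exons (0.0465). The 5′ UTRs held 26 summits (0.444%) against 0.761% of bases (adjusted p = 0.00386, exact binomial). Exons of non-coding genes held 52 summits (0.887%) against 0.824% of bases, a difference that did not pass the test (adjusted p = 0.563, exact binomial).

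Peaks were sparse on chromosome 4, and differences among the large arms were small and changed with the background. The X chromosome held 1076 optimal peaks (18.4%) against 17.1% of the length, and its replicate mean was 18.5% ± 0.944 (SD, n = 3). The embryos were of both sexes, so X was present at a lower mean copy number than the autosomes. None of the tests below adjusted for this. Chromosome 4, a small and largely heterochromatic chromosome, held 17 peaks (0.29%; exact 95% interval 0.169 to 0.464) against 0.971% of the length. The exact binomial test adjusted over 7 chromosomes gave p = 3.18e-09 for chromosome 4 and p = 0.0231 for X. The X difference was lost (p = 0.114, exact binomial, unadjusted) when the Y chromosome, on which no dm6 list held a region, was left out of the length, and in the 2931 peaks with the highest signal (17.7%, exact binomial p = 0.378). It was kept in the dm3 list (18.5%, exact binomial p = 0.00771) and against X's 16.5% share of transcript starts (adjusted p = 0.000201, exact binomial). Against transcript starts, 3L also lay above its share (21.5% against 19.2%, adjusted p = 1.77e-05), 2R lay below (17.5% against 20.5%, adjusted p = 8.41e-09), and 2L did not differ past the threshold (18.5% against 19.4%, adjusted p = 0.0933, exact binomial tests). Chromosome arm 2L, with 1084 peaks (18.5%) against 17.2% of the length, passed against length (adjusted p = 0.0169, exact binomial), and this too was lost without Y (adjusted p = 0.143, exact binomial). Without Y, 2R fell below its share of the length (17.5% against 18.9%, adjusted p = 0.0124, exact binomial). Leaving Y out was chosen after seeing the data.

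The strongest peak of the whole data set lay at the promoter of CG13775 itself. It spanned 6955935 to 6957487 on 2L (dm6), with its summit at 6956925, which is 25 bp inside the 5′ end of CG13775 (FBgn0031874; 6954357 to 6956950, minus strand). The adjacent gene CG3430 (FBgn0031875) starts at 6957008 on the plus strand, so the peak covers the start of both divergent genes. Its signal of 35700.5 was the highest in the pooled list, 1.7-fold above the next region and 133-fold above the median optimal peak. It ranked first in each of the 3 replicate lists, where its signal exceeded that of the next region 1.72-fold in replicate 1, 1.54-fold in replicate 2 and 1.81-fold in replicate 4. Signal values were called separately in each list and are compared within lists only. A transgene that carries CG13775 sequence can add copies of this locus. Within 20 kb of its TSS the pooled list held 24 regions and the annotation 14 gene starts; 3464 protein-coding genes with a similar number of starts (at most 2 more or fewer) had a median of 13 regions, and 96.3% of them had fewer than 24. The 101 bp centred on the summit, on the plus strand, read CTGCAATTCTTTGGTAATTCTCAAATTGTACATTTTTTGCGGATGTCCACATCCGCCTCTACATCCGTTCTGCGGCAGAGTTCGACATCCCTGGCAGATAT.

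**Figure D2:**
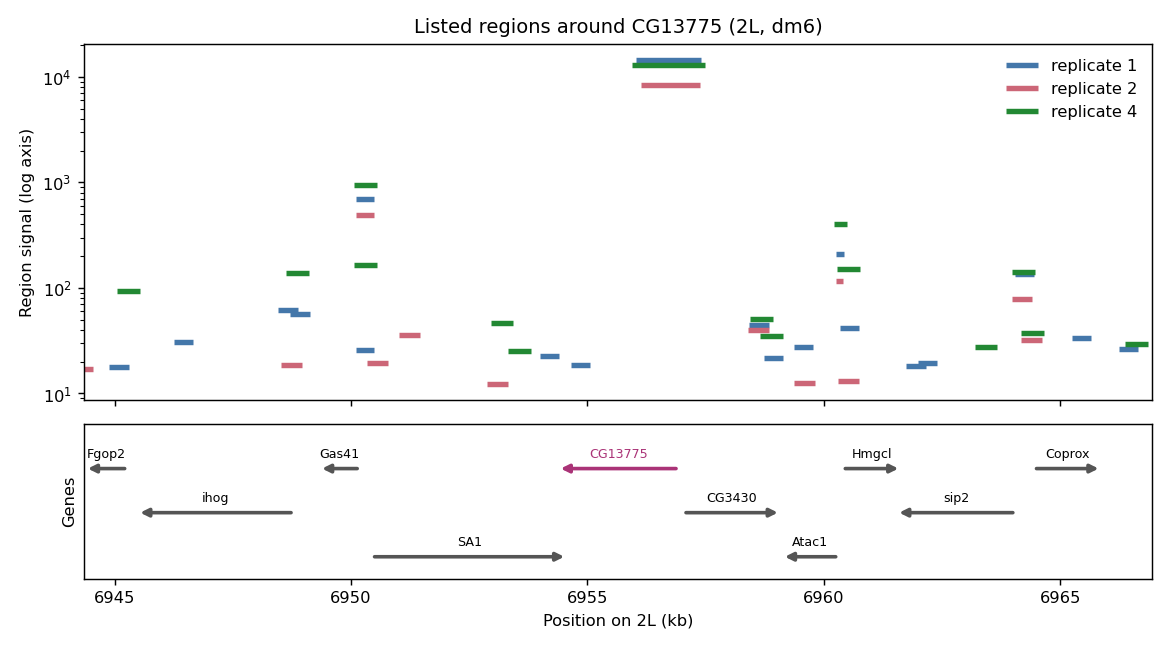
Regions listed in each replicate around CG13775 on 2L of dm6 (horizontal axis, position in kb), drawn to scale at their signal (vertical axis, log scale; values are comparable within a replicate only), with protein-coding genes as arrows in the direction of transcription. In each of the 3 replicates the region over the shared start of CG13775 and CG3430 stands far above the others.

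Of the 25 optimal peaks with the highest signal, 17 had a TSS within 500 bp of the summit, and 10 lay near the starts of more than 1 gene. All 25 ranked among the top 48 regions of every replicate. The peak of the second-highest signal (20956; 29932622 to 29933786 on 3R) lay 49 bp upstream of CG42557 (FBgn0260759), with the starts of CG42558 and Cog7, a subunit of the conserved oligomeric Golgi complex, within 500 bp. Around its summit at 29933238 the plus strand read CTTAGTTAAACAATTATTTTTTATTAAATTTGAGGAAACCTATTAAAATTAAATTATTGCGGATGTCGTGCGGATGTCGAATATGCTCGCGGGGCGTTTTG. The third peak (signal 11108; 22874067 to 22874995 on 2R) lay 123 bp upstream of PIP5K59B (FBgn0034789), which encodes a phosphatidylinositol phosphate kinase. The fourth (9698; 1312947 to 1313944 on 3L) lay between Herc4 (FBgn0035207), a HECT-type ubiquitin ligase gene, and sturkopf. Those 4 peaks took ranks 1 to 4 in the same order in every replicate. The fifth (4564; 15583387 to 15584217 on 3L) lay 176 bp inside AIMP2 (FBgn0036515), whose product belongs to the multi-tRNA synthetase complex.

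Among the remaining 20, the signal ranged from 2258 to 4143. Promoter peaks lay at CG14100, at und (methionine aminopeptidase 2) with Taf11 (a TFIID subunit), at Chro (Chromator) with Ssl1 (a TFIIH subunit), at px, at Ugalt (a UDP-galactose transporter), at Art3 (an arginine methyltransferase) with mRpS10, at Tcs5 with CHMP2B, at CG5611 with Mtl, at mRpL41, at Fkbp14, at Lon (the mitochondrial protease) with PIG-F, and at CG1888. The other 8 had no TSS within 500 bp. Introns of CG11050 (summit at 6612715 on 2L), ush (481064 on 2L, nearest TSS that of cbt), Trl (14759524 on 3L), HmgZ (21703423 on 2R), Lk6 (11761046 on 3R) and CG32772 (4910364 on X) held 6 of them. Trl encodes GAGA factor and HmgZ an HMG-box chromosomal protein. A further peak (12751333 on X) lay in an exon of lncRNA:Vinr, and the last (13035345 on 2R) was intergenic, 11911 bp from the nearest TSS, that of CG13323.

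Genes of the translation machinery and of chromatin architecture had peaks at their starts more often than other genes. Among genes with any pooled region at the start, a set chosen after seeing the data, only cytoplasmic ribosomal protein genes kept this difference past the test. That set keeps every bound gene and drops only unbound ones, so a lost call there does not show that a list does not differ. In all, 3658 of 13968 protein-coding genes (26.2%; exact 95% interval 25.5 to 26.9) had an optimal summit within 500 bp of a TSS, and the restricted replicate lists gave 25.9% ± 1.27 (SD, n = 3). Among 24 gene lists fixed before the data were examined, 5 were bound more often and 6 less often than the other genes of their class (Fisher's exact test, two-sided, Benjamini-Hochberg adjustment over the 24 lists). A bound gene here is one with a listed peak, which can lie closer to a neighbouring gene's start. Genes with a divergent neighbour were counted as bound more often (below), and the lists were not matched for this. The series holds no library from an untagged line or an input, and the kind of the named control is not stated. Enrichment that does not depend on the tagged protein, for example at highly transcribed promoters, therefore cannot be separated from binding.

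Cytoplasmic ribosomal protein genes stood at the top of these lists, with 76 of 86 bound (88.4%) against 25.8% of other protein-coding genes (adjusted p = 1.51e-32, Fisher's exact test). The replicates gave 86% ± 2.01 (SD, n = 3). Their peaks were also strong, with a median signal of 600 against 268 for all optimal peaks, and examples among the strongest lay at RpS27 (1761), RpL7 (1756) and RpL32 (1393). Mitochondrial ribosomal protein genes were bound at 39 of 73 (53.4%; 53.4% ± 4.94 in the replicates, SD, n = 3; adjusted p = 2.19e-06, Fisher's exact test, and 0.195 among genes with any pooled region at the start), with the highest signal at mRpS10 (2597), mRpL41 (2374), mRpS23 (1820) and mRpL23 (1730). Of the translation factor genes, 11 of 16 were bound (68.8%; adjusted p = 0.000959, and 0.178 among genes with any pooled region at the start, Fisher's exact tests), led by the release factor genes eRF3 (651) and eRF1 (467), eEF5 (463) and eEF1alpha1 (415). In the 2931 peaks with the highest signal, 37.5% of translation factor genes were bound against 16.4% of other genes, and this difference did not pass the test (adjusted p = 0.0704, Fisher's exact test).

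Genes for insulator proteins were bound at 11 of 15 (73.3% in the optimal list and 73.3% ± 0 in the replicates, SD, n = 3; adjusted p = 0.000432, and 0.0923 among genes with any pooled region at the start, Fisher's exact tests). The highest signal lay at Chro (3233), Cp190 (1564), M1BP (1004) and pzg (945), and no summit lay within 500 bp of a start annotated to Ibf1, Ibf2, ZIPIC or mod(mdg4). Transcription units annotated separately as pre-mod(mdg4) did have peaks. The peak counted for Dref lay closer to the start of RpL13 (13 bp against 71 bp) and was counted in that gene's list too. Polycomb and trithorax group genes, which encode chromatin regulators that keep developmental genes silent or active, were bound at 13 of 19 (68.4%; 63.2% ± 9.12 in the replicates, SD, n = 3; adjusted p = 0.00037, and 0.0606 among genes with any pooled region at the start, Fisher's exact tests). They were led by ph-p (2084), brm (1611), E(z) (1203) and Su(z)12 (848). The peak counted for trr lay closer to the start of mRpL16 (122 bp against 184 bp) and was counted in that gene's list too.

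Chemoreceptor and cuticle protein genes carried no peak at a TSS. None of 93 cuticle protein genes, 60 odorant receptor genes and 60 gustatory receptor genes was bound, with upper 95% limits of 3.89%, 5.96% and 5.96% (adjusted p = 4.19e-12, 6.57e-08 and 6.57e-08, Fisher's exact tests). Of the genes transcribed into small RNAs, 17 of 295 tRNA genes (5.76%) and 20 of 275 small nucleolar RNA genes (7.27%) had a summit within 500 bp, against 21.9% of other genes in each case (adjusted p = 3.15e-13 and 5.44e-10, Fisher's exact tests). Many of these genes lie in clusters, and with starts within 1000 bp of each other counted once, chosen after seeing the data, the shares were 8.47% of 177 and 13% of 123 (adjusted p = 1.22e-05 and 0.0344, Fisher's exact tests). The tRNA genes with the highest signal nearby were tRNA:Tyr-GTA-1-8 (1376), tRNA:Phe-GAA-1-2 (636), tRNA:Gln-TTG-2-1 (538) and tRNA:Trp-CCA-2-2 (463). For small nucleolar RNA genes they were snoRNA:Or-CD11a (1363), snoRNA:U49:66Da (1182), and snoRNA:Psi28S-2949 and snoRNA:Or-aca5, which share a peak (1113). The summits near snoRNA:Or-CD11a, snoRNA:U49:66Da and tRNA:Phe-GAA-1-2 lay closer to the starts of cytoplasmic ribosomal protein genes and were counted in that list too. When 1000 bp was allowed, 24% of small nucleolar RNA genes counted as bound and their difference was lost. None of the 111 replication-dependent histone genes was bound (adjusted p = 4.06e-14, Fisher's exact test), but their repeated cluster (21416953 to 21541681 on 2L) held no region in any dm6 list, so its absence cannot be told from reads that could not be placed.

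**Figure D3:**
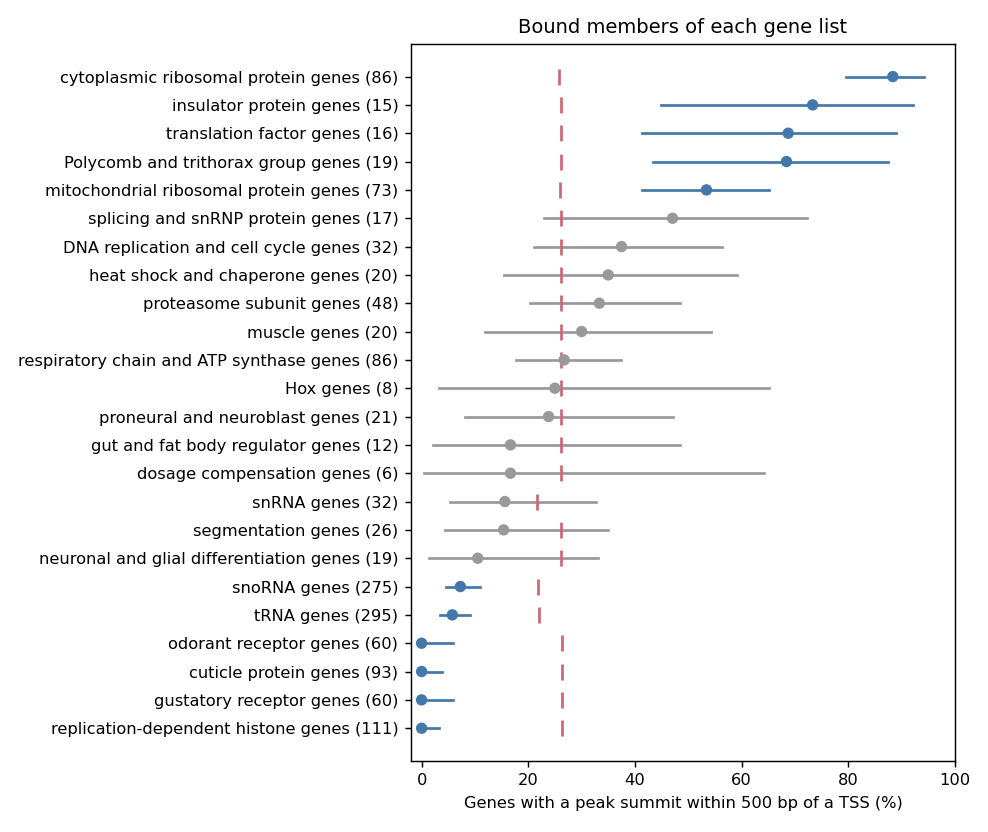
Percentage of genes in each list (number of genes in brackets) with an optimal summit within 500 bp of a TSS, with exact 95% intervals; blue marks lists that differed from other genes (adjusted p below 0.05, Fisher's exact test), grey those that did not, and red ticks the percentage among the other genes of the same class. Cytoplasmic ribosomal protein genes reach 88.4%, and 4 lists have no bound member.

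The other 13 lists did not pass the test with all optimal peaks at 500 bp. Respiratory chain and ATP synthase genes were bound at 23 of 86 (26.7%) and proteasome subunit genes at 16 of 48 (33.3%), neither past the test (adjusted p = 1 and 0.401, Fisher's exact tests). Replication and cell cycle genes gave 12 of 32, splicing and snRNP protein genes 8 of 17, and heat shock and chaperone genes 7 of 20. With 250 bp allowed, splicing and snRNP protein genes passed the test (47.1% against 21.3% of other genes, adjusted p = 0.0325, Fisher's exact test). In the 2931 peaks with the highest signal, none of 32 small nuclear RNA genes was bound against 13.5% of other genes, which passed as well (adjusted p = 0.0374, Fisher's exact test). Among developmental regulators, bound genes were 2 of 8 Hox genes, 4 of 26 segmentation genes, 5 of 21 proneural and neuroblast genes and 2 of 12 gut and fat body regulator genes. Neuronal and glial differentiation genes gave 2 of 19, muscle genes 6 of 20, dosage compensation genes 1 of 6 and small nuclear RNA genes 5 of 32. The smaller lists leave wide intervals, such as 3.19 to 65.1% for Hox genes. In an alternative chosen after seeing the data, only genes with any region of the pooled list within 500 bp of a TSS were entered. The optimal peaks are part of the pooled list, so every bound gene stays in this set and only unbound genes leave it. There, cytoplasmic ribosomal protein (91.6%), cuticle protein (0%) and tRNA genes (16.8%) kept their difference. Mitochondrial ribosomal protein (59.1% against 48.4% of other genes), insulator protein (78.6%), Polycomb and trithorax group (81.2%), translation factor (73.3%), odorant receptor (0 of 4), gustatory receptor (0 of 7) and small nucleolar RNA genes (29.9% against 45.5%) no longer passed, and histone genes could not be entered. Lists had fewer members there and more of the other genes were bound, and which of these ended the calls was not tested.

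Genes with a divergent neighbour were counted as bound more often than others. Of 4650 protein-coding genes whose TSS had that of a gene on the opposite strand within 1000 bp upstream, 2231 (48%) were bound, against 1427 of 9318 others (15.3%), an odds ratio of 5.1 (Fisher's exact test, two-sided, p under 1e-300). The replicates gave 47% ± 2.4 and 15.4% ± 0.704 (SD, n = 3). A summit between divergent starts can count for both genes. With 1 gene per pair, an alternative chosen after seeing the data, the odds ratio was 5.06 (Fisher's exact test, p = 3.17e-222). The gene kept can still count as bound through a summit at its partner's start, so this does not remove the advantage of another start in reach. With a summit required within 100 bp, also chosen after seeing the data, 18.5% of paired genes and 5.23% of others were bound (odds ratio 4.12, Fisher's exact test, p = 2.28e-129). The share that the partner's start alone would give was not computed.

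On average, summits fell on short AT-rich stretches. The 101 bp centred on optimal summits had a GC content of 34.2%, whereas windows of the same width centred 300 bp to one side had 44.2%. The replicates gave a difference of −9.59 percentage points ± 0.39 (SD, n = 3). GC content was lower than in the flank at 75.2% of optimal summits, so this did not hold at every peak. Among the 5 peaks with the highest signal, those ranked 1, 3 and 5 had 45.5, 47.5 and 57.4% GC at the summit, above the 42.1% of the chromosome arms. Those ranked 2 and 4 had 33.7% each. All of the 10 6-mers chosen on 2L and 2R for their excess at summits contained only A and T, and all 10 were again more frequent at the 3738 summits on 3L, 3R and X. TTAAAA, for example, occurred in 33.6% of summit windows and 15.6% of flank windows (adjusted p = 3.4e-69, exact McNemar test).

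**Figure D4:**
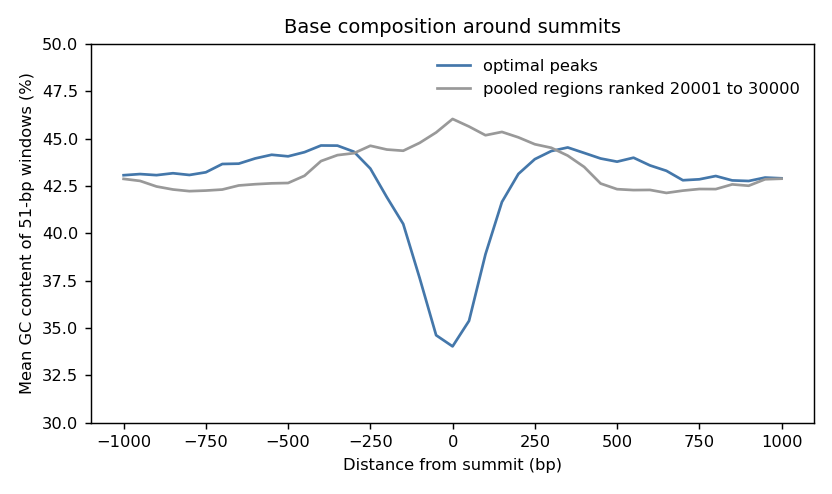
Mean GC content (%) of 51-bp windows against distance from the summit (bp), for the 5862 optimal peaks and for the 10000 lowest-ranked regions of the pooled list. The optimal peaks dip to about 34% at the summit and the lowest-ranked regions do not.

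Of 18 sequence words fixed before the data were examined, 8 were more frequent and 5 less frequent at summits than in the flanks (exact McNemar tests, two-sided, Benjamini-Hochberg adjustment over the 18 words). The DRE word TATCGATA, bound by Dref and BEAF-32, occurred in 2.34% of summit windows and 0.478% of flank windows (adjusted p = 1.77e-18, exact McNemar test). At TSS-proximal summits its share was 4.14%, and at summits over 500 bp from any TSS it was 0.257% and no longer differed from the flank. CGATA, the core of that word, showed the same split between proximal summits (22.9% against 14%) and distal ones (10.4% against 9.83%). The M1BP word GGTCACACT rose from 0.375 to 0.938%, the Su(Hw) core word TGCATAYTTT from 0.136 to 0.495% and the Ohler 6 promoter word KTYRGTATWTTT from 0.0853 to 0.461% (adjusted p = 0.000239, 0.00113 and 0.000226, exact McNemar tests). These 3 words were rare at distal summits (0.147, 0.367 and 0.11%), where none passed and the test had little power. In the 2931 peaks with the highest signal, the M1BP word had 0.546% against 0.307% and did not pass. TATAAA rose from 10.3 to 22% and AAAAAA from 18.4 to 26.8%, and WGATAR, the GATA factor word, rose from 14.9 to 21.5%; all 3 are AT-rich and kept their difference at distal summits.

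The words that were less frequent at summits each hold at least as many G and C as A and T bases. GAGAG, bound by GAGA factor, occurred at 9.28% of summits and in 15.3% of flanks, CACACA at 6.31 and 12%, GCCAT at 14.1 and 17.9%, CACGTG at 0.887 and 1.69%, and AGGTCA at 1.69 and 2.35% (adjusted p from 7.42e-26 for CACACA to 0.0175 for AGGTCA, exact McNemar tests). The AGGTCA difference did not pass in the 2931 peaks with the highest signal, and at TSS-proximal summits neither AGGTCA (1.85 and 2.07%) nor CACGTG (1.12 and 1.72%) passed. The Zelda word CAGGTAG (0.426 and 0.529%), the CTCF core word AGGTGGCG (0.478 and 0.324%), the initiator word TCAGTY, the AP-1 word TGACTCA and CAGCTSWW did not differ past the threshold over all summits; at TSS-proximal summits TCAGTY was less frequent (7.81 and 10%, adjusted p = 0.00436, exact McNemar test). Words were counted as exact matches on either strand, and the shift in base composition at summits by itself raises AT-rich words and lowers GC-rich ones.

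**Figure D5:**
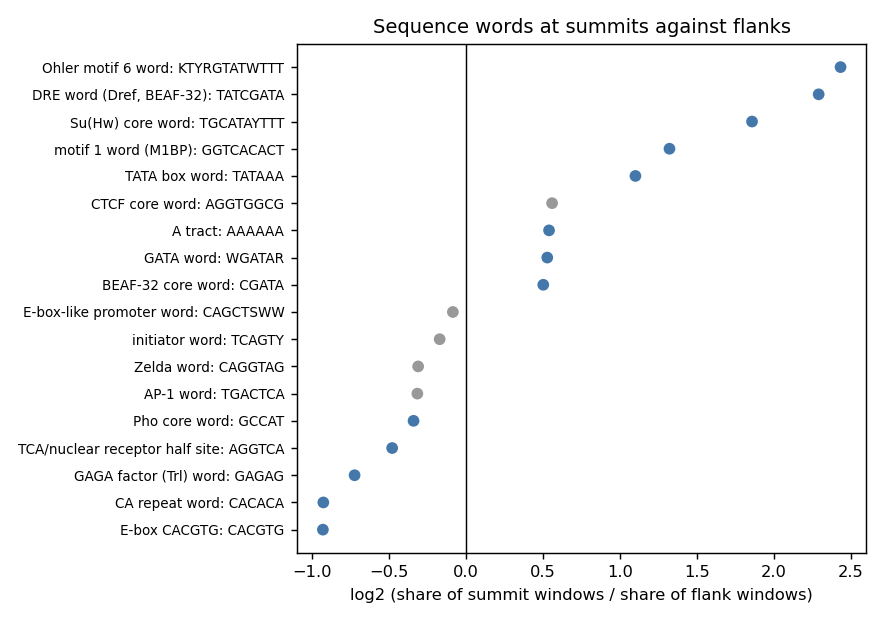
Ratio, on a log2 scale, of the share of summit windows to the share of flank windows that hold each of 18 sequence words, over 5862 optimal peaks; blue marks words with an adjusted p below 0.05 in the exact McNemar test and grey the others. TATCGATA, for example, lies to the right and GAGAG and CACACA to the left. The initiator word TCAGTY and the promoter word CAGCTSWW also lie to the left, in grey.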

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

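The dm3 list of the pooled libraries held 35 regions on sequences outside its main chromosome arms, 13 of them on 3LHet with a best rank of 4166 of 30000; this is a signal in data outside the main measurement, which used dm6. No coordinates were converted, so whether the dm6 lists hold the same regions was not examined.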

How the results depend on the processing

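Alternatives that left Y out of the background, took lower-ranked regions as background, counted 1 gene per divergent pair, required a summit within 100 bp of the start, counted list members with neighbouring starts once, or entered only genes with a pooled region at the start were chosen after seeing the data. Single lists and words were followed only if they passed the main test. Changes among the other lists and words, some of which changed side without passing, are not in these counts. No followed result reversed under any of the 157 alternative values. Of these, 125 were the same (same side of the threshold, within the spread, or for a count within 1.5-fold of it), 18 were weaker and 14 moved. Within that wide limit, peaks supported in every replicate went from 4297 (73.3%) to 3624 (61.8%) with summits within 100 bp, 3244 (55.3%) with 50% reciprocal overlap and 5543 (94.6%) with 11724 regions per replicate. The share of summits near a TSS ranged from 42.7 to 63.2% over its alternatives, each above its background. Its lowest value came with 250 bp (background 7.35%) and its highest with 1000 bp (background 23.2%). The odds ratio for divergent promoters ranged from 4.12 to 5.53. With the upper part of the optimal list by signal, the number of peaks was by construction 2931, bound protein-coding genes fell to 16.4%, and the X share was 17.7% and no longer past the threshold. Leaving Y out ended the X difference at an unchanged 18.4%, because the expected share rose to 17.6%. The share of bound protein-coding genes was 21.4% at 250 bp, 29.3% at 1000 bp and 20.6% with peaks supported in every replicate. With 2931 regions per replicate, 2390 peaks were supported in every replicate. Pairwise overlap was 71.5% with summits within 100 bp, 71.3% with 50% reciprocal overlap, 71.8% with 11724 regions per list and 83.4% with 2931; leaving out a replicate gave 80.2 to 82.3%, and a rank correlation of 0.80 to 0.844. Of 11 gene lists past the test, 3 remained when only genes with a pooled region at the start were entered. That set has fewer members per list and a higher share of bound genes, since only unbound genes leave it. Of 13 words, 8 passed at summits over 500 bp from any TSS. For the moved and weaker values whose construction does not give it, the cause was not tested. Among single lists and words, 88 alternative values kept their call and 16 lost it. The X share of the dm3 list was set against dm6 lengths. Depth is unknown, so how many weaker sites were missed cannot be said.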

Other observations

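The tests of the CG13775 locus and of the word TGCGGATG were chosen after their results were seen; those of base composition were set before.

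Non-coding genes were examined by class, without a test between classes. Of 3289 long and other non-coding RNA genes, 253 (7.69%; 7.56% ± 0.228 in the replicates, SD, n = 3) had an optimal summit within 500 bp of a start, and of 330 pseudogenes 9 (2.73%; 2.42% ± 0.303, SD, n = 3) did. Annotated transposable elements make up 5.93% of the arms and held 21 optimal summits (0.358%), and the lower-ranked regions of the pooled list held 0.365%; reads in repeats often cannot be placed, so these shares do not show that such elements were unbound. Distal binding was nonetheless common, with 2725 optimal summits over 500 bp from any TSS and 775 (13.2%) over 5000 bp away.

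The word TGCGGATG, noticed in the sequence under the strongest peaks, occurred within 50 bp of the summit in 4 of the 5 peaks with the highest signal, and 6 copies of its core GCGGAT, on either strand, lay in the region at CG13775. Among the peaks ranked 51 and lower, which were not used to choose it, it occurred at 101 of 5812 summits (1.74%) and in 24 flank windows (0.413%; exact McNemar p = 1.22e-12), which argues against chance in choosing the word. Its summit-to-flank ratio, 4.08 with a small constant added to both counts, stood at the 99.9th percentile of 839 words made of the same bases, whose median ratio was 0.6, which argues against base composition. The excess was larger at summits over 500 bp from any TSS (2.69% against 0.479%) than near one (0.904% against 0.355%), a difference not itself tested; it was present in all 3 replicate lists (1.93, 1.72 and 1.45%), and on 4 of 5 arms it passed the exact McNemar test (on 2R, 0.793% against 0.297%, adjusted p = 0.227). Of 5743 copies on the arms, 3.1% were within 50 bp of an optimal summit; whether the word contributes to binding was not tested.

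The peak at CG13775 may be raised by the transgene. If the transgene carries extra copies of the neighbourhood, regions should be dense around the gene, and 24 pooled regions lay within 20 kb of its TSS, at the 96.3rd percentile of 3464 protein-coding genes with a similar number of gene starts (median 13; 96.6th percentile of all); this fits extra copies but is weak support, since it is 1 locus and the activity of its genes was not matched. The next signal within 20 kb (2122; 6950077 to 6950534 on 2L) was 16.8-fold lower. Dividing the peak by the ratio of the median signal of the other regions within 20 kb to that of the pooled list (1.16) would leave it at rank 1, but regions enter the list only above a floor, so that ratio does not measure copy number. Extra transgene copies as the whole cause, binding of the protein to its own promoter and an effect of the tag or antibody cannot be told apart, since there is no library from an untagged line.

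The AT-rich summits were not limited to promoters: at summits over 500 bp from any TSS, GC content was −10.9 percentage points relative to the flank (SE 0.266), much as at all optimal summits (−9.97). In the 10000 lowest-ranked regions of the pooled list it was 1.51 points above the flank (SE 0.133), so a bias shared by all listed regions is argued against. Of 200000 random positions, weighted to the GC content of the optimal summits and their flanks, 1.69% lay within 100 bp of an optimal summit, against 0.851% without weighting. The number of summits and their base composition by themselves give 1.87%, far below the 50% set beforehand for such a bias, so this test decides nothing, and a sequencing or amplification bias for such base composition as the whole cause stays open. A preference for AT-rich DNA, or for the nucleosome-poor sites that such sequence often marks, is another candidate explanation that these files could not test.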
